A study of Mus musculus with 8 samples.

How the data were processed

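Whole liver was profiled by RNA sequencing in 4 AgRP activated and 4 control samples, 4 hours after CNO. Per the labels' protocols, RNA was isolated with Trizol and a column and poly(A) selected, and the submitters' processing notes name genome build GRCm38. The aligner, the read counter, its strand setting and the annotation release are not given in the sources used here. Each deposited column of values is a signal of gene counts divided by 1 size factor per library by the authors, as the values show: 100% of the values were whole multiples of 1 step per column within 0.01 of a read. The whole reads recovered in this way gave the depth of each library. The table lists 14801 genes, the least covered with 81 reads over 8 libraries, so it had passed a minimum that no header states. The deposited table also holds a log2 fold change, p-value and adjusted p-value of the authors, whose column names are those DESeq2 writes; DESeq2 run on the recovered reads gave log2 fold changes within 2.58e-05 of the deposited ones. Columns not used number 0.

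Control columns carry their group's name and number. The other 4 columns carry an undefined code and were taken as the AgRP activated group by elimination, without a link between a column and a particular mouse. The labels list separate samples and do not say in so many words that each came from a separate animal; p-values measure the spread between these samples. No 2 libraries of a group agreed within counting noise, with a chi-square per degree of freedom of at least 36.9.

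The test, the filter, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined; tests on recovered reads, and estimated correlations after a correction or without a library, were added after. Because the values are scaled and not counts, limma 3.58.1 in R 4.3.3 was fitted with trend and robust settings to log2(value + 1), over 14800 genes with a value of at least 1 in at least 4 libraries, with no covariate and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates the change of genes with few reads. The 34 gene lists were tested with camera at a preset correlation of 0.01, with the correlation estimated per list and with fry beside it, adjusted over the 33 lists with at least 3 genes measured; the list of pancreatic acinar genes had fewer. Counts of members are over all genes tested, and those adjusted over the list alone are given beside them where they differ. By fry, which asks whether the genes of a list move on balance 1 way, 4 lists passed: glucocorticoid-induced, PPARalpha, gluconeogenesis and B cell genes. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. Replicate numbers were tried as a block, single libraries were left out in turn, and the normalization, filter, pseudocount, threshold and scaling were varied.

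The genes named were, among those past the threshold with no overlap between groups and a mean value of at least 1, the 10 with the largest rise and the 10 with the largest fall; up to 3 members per list with the smallest adjusted p, or 2 by p where none passed; genes the design or the fasting response point to; and sex-linked genes. Predicted genes were left out, and some genes the rule names are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Of the gene identifiers 14770 were found in GENCODE mouse release M21 (GRCm38), the source of positions.

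On simulated libraries with the real means and depths, 200 of 14801 genes were changed. Limma recovered 34.3% of genes changed 1.5-fold, 59.7% changed 2-fold and 100% changed 4-fold, and 13.4% of its calls were false, above the nominal share. The false share was 12.8% for edgeR and 24.1% for DESeq2. These shares come from a single simulated draw. Of 25 simulated lists, all 5 shifted ones and 0 of 20 unchanged ones were called. The simulated genes were drawn independently, so this does not show how often camera at the preset correlation errs on correlated genes. Estimated correlations of the real lists called ran from -0.0247 to 0.707. Tests were two-sided. With 4 libraries against 4, the smallest p an exact permutation test can give is 0.0286. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.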

Results

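The data were poly(A)-selected RNA sequencing profiles of whole mouse liver, taken 4 hours after clozapine N-oxide (CNO) at 1 mg per kg. AgRP neurons are hypothalamic neurons whose activity drives hunger. In the 4 AgRP activated samples, Cre recombinase under the Agrp gene switched on hM3Dq, an engineered receptor through which CNO excites the neurons that carry it. The 4 controls carried the receptor construct without Cre and received the same CNO, so the contrast holds the drug constant. The comparison asks whether the liver transcriptome differs when hypothalamic hunger neurons are activated. Food access during the 4 hours is not in the sources used here. The reads recovered per library ranged from 22993908 to 46717420, with a mean of 38901084 (SD 6514208, n = 4) in the AgRP activated group and 33958600 (SD 8559161, n = 4) in controls. Control columns carry the group's name. The other 4 columns carry a code that no label defines. They were assigned to the AgRP activated group because no other group remained, so every direction below rests on that assignment. Their numbers (AgRP library 1 to 4) are the columns' own.

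AgRP activation was accompanied by a broad change in liver expression. Genes induced by glucocorticoids and enzymes of amino acid catabolism and cholesterol synthesis were among those that rose. Targets of the fatty-acid receptor PPARalpha and markers of B cells were among those that fell. The largest rises were those of Fam107a, a glucocorticoid-responsive gene (log2 fold change 4.69), the cytochrome Cyp2b10 (4.45), the estrogen sulfotransferase Sult1e1 (3.84) and the cell-cycle inhibitor Cdkn1a (3.67). The largest falls were those of the acyl-CoA thioesterase Acot3 (-4.65), the glycogen-targeting subunit Ppp1r3g (-3.02), the fatty-acid hydroxylase Cyp4a14 (-2.95) and Nrep (-2.93). Greb1 (3.06), Orm3 (2.77), Zbtb16 (2.74), Jaml (2.63), Tmem100 (2.60) and Ppp1r3c (2.54) completed the 10 largest rises whose groups did not overlap. Cda (-2.76), Slc25a30 (-2.69), Rab30 (-2.49), Cish (-2.48), Rfx4 (-2.45) and Socs2 (-2.43) completed the 10 largest falls. Of 14800 genes tested with limma, 317 were higher and 454 lower in AgRP activated liver at an adjusted p under 0.05, and 3096 had an unadjusted p under 0.05. The 4 values of each group did not overlap for 2118 genes (14.3%), against 2.86% by chance. With a single library left out the total fell to 357 (without control 4), 369 (without control 1), 372 (without AgRP library 4), 408 (without control 3), 416 (without control 2) and 462 (without AgRP library 1). Adjusted p rose to 0.0777 for Sult1e1 and 0.0553 for Greb1 without AgRP library 4, and to 0.0977 for Orm3 without AgRP library 3. Without control 4 it was 0.0579 for Acot3, 0.0780 for Cish and 0.0571 for Socs2.

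Glucocorticoid-induced genes, which the adrenal hormone corticosterone switches on in liver, formed the most strongly raised list. Of 22 measured members 9 rose, none fell and 13 did not pass, with 12 rising when adjusted over the list alone and a median log2 fold change of 1.38. Lpin1, a phosphatidate phosphatase (chromosome 12, 16535669 to 16610966, GRCm38), rose from 6881 ± 1142 to 26667 ± 756 scaled reads (SD, n = 4), a log2 fold change of 1.97 ± 0.12 (SE, limma adjusted p = 0.000219). The transcription factor Zbtb16 (chromosome 9, 48654297 to 48836222) rose from 432 ± 135 to 2817 ± 336 scaled reads (SD, n = 4, log2 fold change 2.74 ± 0.20, SE, limma adjusted p = 0.000818). Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), rose by 1.76 ± 0.27 log2 units (SE, limma adjusted p = 0.0111). Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose by 1.59 ± 0.33 (SE, limma adjusted p = 0.0327). The receptor gene itself, Nr3c1, had a log2 fold change of -0.02 ± 0.08 (SE, limma adjusted p = 0.914), and Per1 had 0.37 ± 0.31 (SE, limma adjusted p = 0.570). The list ranked above other genes by camera with a preset correlation (adjusted p = 1.39e-11), but not past the threshold with each list's own correlation (adjusted p = 0.137 with an estimated correlation). The count of members that rose dropped to 6 without AgRP library 1 or without control 4, and Tsc22d3 reached an adjusted p of 0.0841 without control 1.

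**Figure D1:**
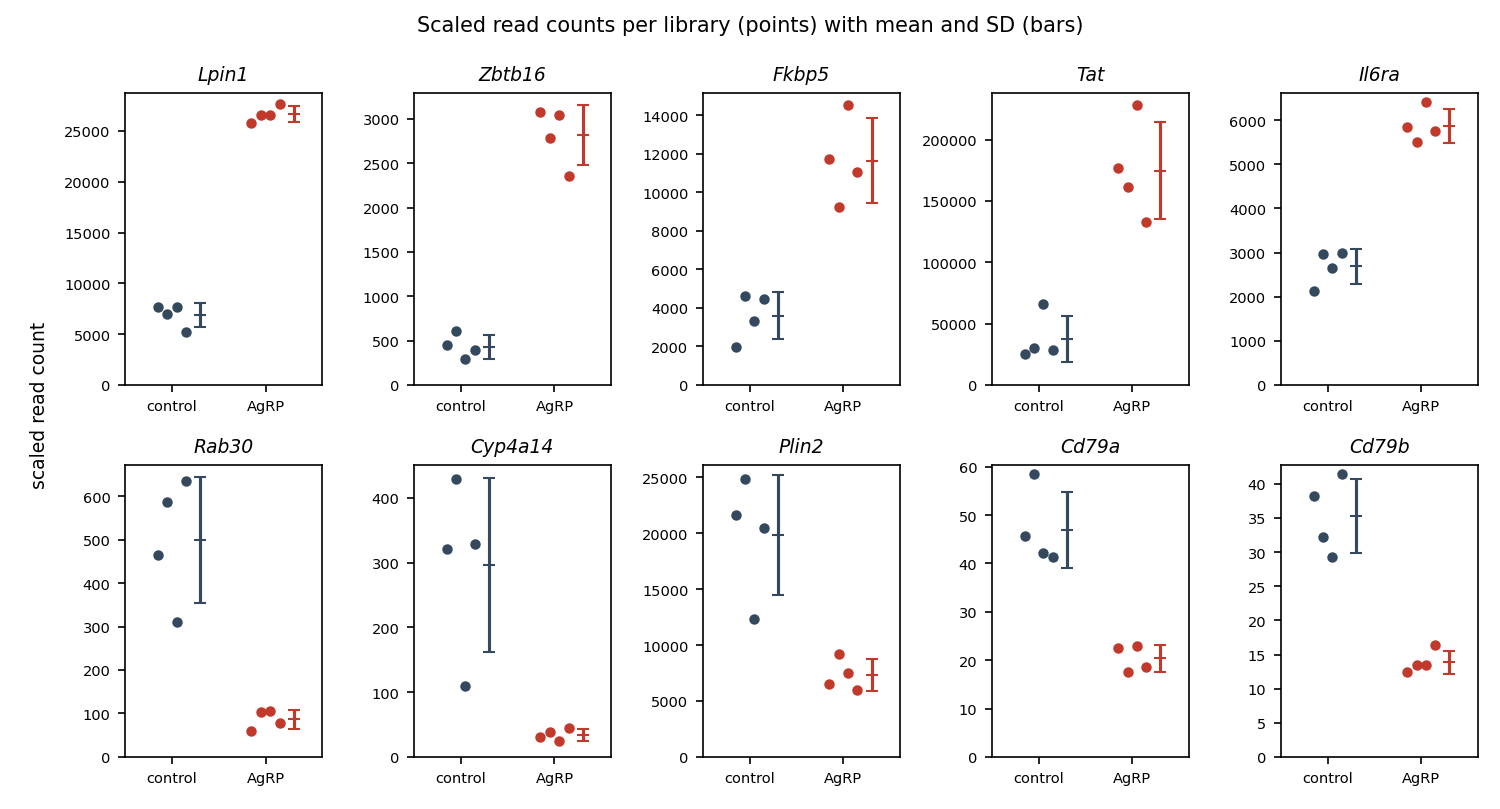
Scaled read counts (vertical axes, each from 0) of 10 genes in the 4 control and 4 AgRP activated libraries, with points for libraries and bars for mean and SD. Lpin1, Zbtb16, Fkbp5, Tat and Il6ra were higher and Rab30, Cyp4a14, Plin2, Cd79a and Cd79b lower in every AgRP activated library than in any control; for Lpin1 the means were 26667 and 6881.

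Targets of PPARalpha, the nuclear receptor that drives fatty-acid oxidation in fasting liver, moved the other way. Of 37 measured members 13 fell, none rose and 24 did not pass. Adjusted over the list alone 26 fell and 1 rose. Plin2, which coats lipid droplets (chromosome 4, 86648386 to 86670060), fell from 19839 ± 5336 to 7313 ± 1438 scaled reads (SD, n = 4), a log2 fold change of -1.41 ± 0.22 (SE, limma adjusted p = 0.0107). The fasting hormone gene Fgf21 had a log2 fold change of -1.93 ± 0.43 (SE, limma adjusted p = 0.0331) at a low level, 6.26 ± 3.83 against 25.3 ± 9.36 scaled reads (SD, n = 4). Acot1 (-1.42), Acot3 (-4.65) and Cyp4a14 (-2.95) also fell. These belong to families of close paralogs among which reads can be split, and their sizes are uncertain. Cpt1a, the entry enzyme of mitochondrial fatty-acid oxidation, had a log2 fold change of -0.25 ± 0.10 (SE, limma adjusted p = 0.20), Pdk4 0.13 ± 0.23 (SE, limma adjusted p = 0.811) and Ppara itself -0.21 ± 0.15 (SE, limma adjusted p = 0.470). The list had a median of -0.43 and ranked below other genes by camera (adjusted p = 4.75e-12, and adjusted p = 0.219 with an estimated correlation). The number that fell was 6 without control 2, 7 without control 1 or AgRP library 1, and 8 without control 4, AgRP library 3 or AgRP library 4. Fgf21 reached an adjusted p of 0.0893 without control 1.

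In the list of gluconeogenesis and amino acid catabolism, 5 of 26 measured members rose, none fell and 21 did not pass, and 13 rose when adjusted over the list alone. Tat, tyrosine aminotransferase, rose from 37466 ± 18974 to 174760 ± 39801 scaled reads (SD, n = 4, log2 fold change 2.31 ± 0.30, SE, limma adjusted p = 0.00570). Tdo2, tryptophan dioxygenase, rose by 0.79 ± 0.10 (SE, limma adjusted p = 0.00344). Sds, serine dehydratase (1.45 ± 0.28, SE), the urea-cycle enzyme Cps1 (0.60 ± 0.13, SE) and the transcription factor Klf15 (0.63 ± 0.16, SE) were the others. The rate-limiting gluconeogenic gene Pck1 had a log2 fold change of 0.50 ± 0.18 (SE, limma adjusted p = 0.147), and G6pc, the last step of glucose release, had -0.88 ± 0.33 (SE, limma adjusted p = 0.177). The list's camera call (median 0.46, adjusted p = 4.55e-08) was lost when its correlation was estimated (adjusted p = 0.498 with an estimated correlation). Tat and Sds also belong to the glucocorticoid-induced list. Adjusted p reached 0.0648 for Sds and 0.0714 for Cps1 without AgRP library 4, and 0.125 for Klf15 without control 1. The count was 8 without control 3, 3 without control 1 or 2, and 2 without AgRP library 2, 3 or 4 or control 4.

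Of 27 cholesterol synthesis genes measured, 5 rose, among them Sqle, Fdps, Dhcr7 and Srebf2, none fell and 22 did not pass. Adjusted over the list alone 12 rose and 1 fell. Sqle rose by 0.87 ± 0.17 (SE, limma adjusted p = 0.0217), and Fdps by 0.37 ± 0.08 (SE, limma adjusted p = 0.0318). The list had a median of 0.43 and a camera adjusted p of 3.92e-08 (adjusted p = 0.498 with an estimated correlation). The count was 9 without AgRP library 3, 2 without AgRP library 1 or 2, and 1 without AgRP library 4 or control 2, 3 or 4. Adjusted p reached 0.0666 for Sqle without control 2 and 0.0801 for Fdps without control 1. Dhcr7 and Srebf2, chosen after their values were seen, kept their calls only without AgRP library 3.

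The acute phase list holds plasma proteins liver secretes in inflammation, with receptors and regulators of that response. Of its 30 measured genes 2 rose, none fell and 28 did not pass, and 4 rose when adjusted over the list alone. Il6ra, the interleukin-6 receptor, rose from 2689 ± 396 to 5878 ± 387 scaled reads (SD, n = 4, log2 fold change 1.14 ± 0.11, SE, limma adjusted p = 0.00145). Orm3, one of 3 close paralogs on chromosome 4, rose by 2.77 ± 0.61 (SE, limma adjusted p = 0.0392). Leaving out AgRP library 2, 3 or 4 or control 1, 2 or 3 left 1 of the 2. Saa1 and Saa2, inducible members chosen after their values were seen, had log2 fold changes of 2.69 ± 1.30 and 3.39 ± 1.63 (SE, limma adjusted p = 0.298 and 0.295), and the spread between replicates was wide. Control 4 held 138070 and 133270 scaled reads of them, against at most 15817 and 7673 in the other controls. The AgRP libraries ran from 31686 to 152030 for Saa1 and from 16581 to 200690 for Saa2. Camera ranked the list above other genes (median 0.50, adjusted p = 7.44e-06, and adjusted p = 0.969 with an estimated correlation). Its median ranged from 0.288 without AgRP library 3 to 0.787 without control 4. Among ER chaperones 0 of 23 passed by limma, 4 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0 and 1. Herpud1, which takes part in ER protein degradation, had a log2 fold change of 0.62 ± 0.18 (SE, limma adjusted p = 0.0815). The list had a median of 0.19 (camera adjusted p = 0.00353, and adjusted p = 0.969 with an estimated correlation). Its call was lost without AgRP library 3 (adjusted p = 0.0643), without control 3 (0.0964) and under quantile normalization (0.0812), and its median ranged from 0.0949 without control 3 to 0.313 without control 1. Periportal hepatocyte markers had 2 of 14 rise (Sds and Cps1), 6 when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.00209, and adjusted p = 0.899 with an estimated correlation). Sds, Cps1 and other periportal members also belong to the list of gluconeogenesis and amino acid catabolism, so the call is not separate from that one. The count for periportal genes was 0 without AgRP library 2, 3 or 4 or control 4, 1 without AgRP library 1 or control 1, and 4 without control 3. Of 14 pericentral markers only Cyp27a1 rose, the list median was 0.09 (camera adjusted p = 0.450), and Cyp27a1 reached an adjusted p of 0.120 without control 1.

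B cell markers fell as a list, though not every member passed. Of 10 measured, 6 fell, among them Cd79a, Cd79b, Ighd, Pax5 and Fcer2a, none rose and 4 did not pass, and 7 fell when adjusted over the list alone. All 10 had lower log2 means in AgRP activated liver. Cd79b, a subunit of the B cell receptor (chromosome 11, 106311341 to 106314762), fell from 35.3 ± 5.48 to 13.9 ± 1.70 scaled reads (SD, n = 4, log2 fold change -1.28 ± 0.22, SE, limma adjusted p = 0.0118). Cd79a, its partner, fell by 1.16 log2 units (SE 0.20, limma adjusted p = 0.0141). Ighm, the mu heavy chain, had a log2 fold change of -0.15 ± 0.75 (SE, limma adjusted p = 0.944), a gene chosen after its values were seen, as were Pax5 and Fcer2a. Of the 8 lists called, this was the only one whose call held with an estimated correlation (median -1.07, camera adjusted p = 1.51e-08, and adjusted p = 0.0240 with an estimated correlation). Without single libraries the value with an estimated correlation ran from 0.0477 to 0.0646, under 0.05 only without AgRP library 1 or 4. These genes have few reads per library. The count that fell was 2 without AgRP library 4, control 1 or control 4, 3 without control 3, and 4 without AgRP library 3 or control 2. Other leukocyte lists had no member that passed by limma: 0 of 14 T and NK cell genes (camera adjusted p = 0.657), 0 of 14 monocyte genes (0.657), 0 of 9 neutrophil genes (0.788) and 0 of 16 Kupffer cell and macrophage genes (0.582). At an unadjusted p under 0.05, limma gave 1, 1, 1 and 2 members of these lists. At an adjusted p under 0.05, edgeR and DESeq2 called 0 in each. Without AgRP library 3, where monocyte genes were highest, the monocyte list ranked lower in the AgRP activated group (median -0.55, camera adjusted p = 0.00651), but not past the threshold with an estimated correlation (adjusted p = 0.906).

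**Figure D2:**
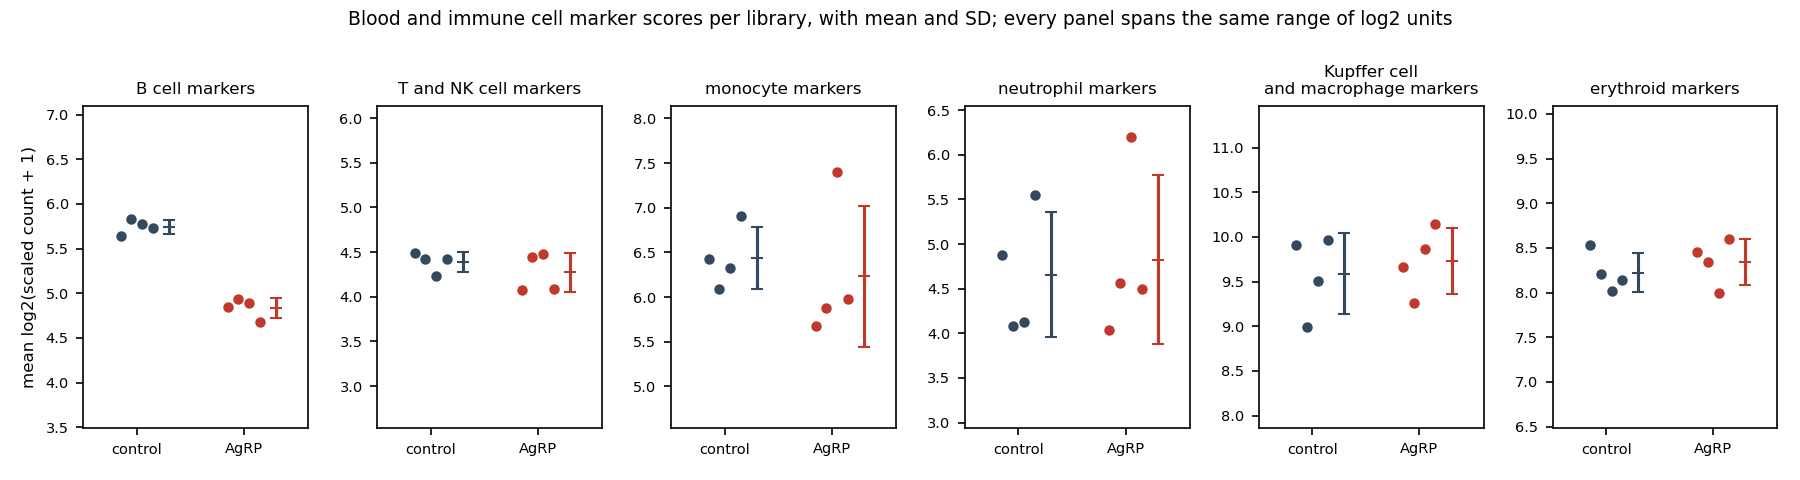
Mean log2(scaled reads + 1) over the members of 6 blood and immune cell marker lists (vertical axis) in each control and AgRP activated library, with bars for mean and SD; each panel spans the same number of log2 units. The B cell score fell from 5.74 ± 0.0790 to 4.84 ± 0.112 (SD, n = 4) with no overlap, and AgRP library 3 was the highest library in the monocyte and neutrophil panels.

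Ccl2, the chemokine that draws monocytes out of the bone marrow, did not differ beyond the spread between replicates, with 49.3 ± 75.6 scaled reads in AgRP activated and 39.2 ± 30.3 in control liver (SD, n = 4, log2 fold change -0.52 ± 0.88, SE, limma adjusted p = 0.800). AgRP library 3 held 163 scaled reads and the other 3 AgRP libraries held 9.27 to 13.5. Without it the log2 fold change was -1.45 (limma adjusted p = 0.118), and edgeR on all 8 libraries gave 0.29 (adjusted p = 0.907). Of 20 chemokines and growth factors measured, only Cxcl12 passed, falling by 0.55 log2 units (SE 0.09, limma adjusted p = 0.0119). Its list was not called (camera adjusted p = 0.657). Of 19 clock genes 1 rose, Ciart (1.12 ± 0.16, SE, limma adjusted p = 0.00753). The 3 that fell were Dbp (-1.35 ± 0.23, SE, limma adjusted p = 0.0158), Nr1d2 (-0.49 ± 0.09, SE, limma adjusted p = 0.0159) and Per3 (-1.25 ± 0.26, SE, limma adjusted p = 0.0314). With p adjusted over the list alone 2 rose and 7 fell, and the list was not called (camera adjusted p = 0.582). Camera asks for a shift 1 way. The mixed form of fry, which asks for changes in either direction, gave an adjusted p of 5.53e-05. Per3 was chosen after its values were seen, and it reached an adjusted p of 0.0739 without control 2. Without control 4 Dbp lost its call and 1 clock gene fell.

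Genes that insulin and feeding induce did not pass as a set. In the lipogenesis and glycolysis list 0 of 26 rose by limma (2 at an unadjusted p under 0.05). At an adjusted p under 0.05, edgeR called 0 higher and DESeq2 1. Mlxipl, a carbohydrate-responsive transcription factor, fell by 0.50 log2 units (SE 0.09, limma adjusted p = 0.0135). Srebf1 and Fasn had log2 fold changes of 0.80 ± 0.35 and 0.55 ± 0.34 (SE, limma adjusted p = 0.241 and 0.409). In the insulin-repressed FoxO1 list Irs2, an insulin receptor substrate, fell by 1.77 log2 units (SE 0.33, limma adjusted p = 0.0229), and Klf15 rose. Adjusted over that list alone 3 rose and 3 fell. Igfbp1 had 0.95 ± 0.94 (SE, limma adjusted p = 0.633). Bile acid genes had 2 of 16 rise, the repressor Nr0b2 (1.16 ± 0.26, SE, limma adjusted p = 0.0404) and Cyp27a1 (0.42 ± 0.10, SE, limma adjusted p = 0.0476). Among cell type lists Hnf4a and Tat rose in the hepatocyte list, Flt1 in the endothelial list and Rrm2 in the cell cycle list, while Lrat fell in the stellate list. The stellate list ranked lower without control 3 (median -0.31, camera adjusted p = 0.00148, and adjusted p = 0.856 with an estimated correlation). Dusp1 (1.32 ± 0.28, SE, limma adjusted p = 0.0355), also of the glucocorticoid-induced list, rose in the immediate-early list and Fgf21 fell in the ATF4 list. Adjusted over the ATF4 list alone 1 rose and 1 fell. In the female-biased list Cyp2b10 rose and Cyp4a14 and Acot3, also of the PPARalpha list, fell. No member passed by limma among interferon-stimulated, autophagy, ribosomal protein, hormone receptor and energy-sensing, cholangiocyte, erythroid, adipocyte and male-biased genes. At an unadjusted p under 0.05 limma gave 3, 6, 0, 6, 1, 0, 0 and 2 of them. At an adjusted p under 0.05 edgeR called 0 in each list, and DESeq2 called 1, 1, 0, 2, 0, 0, 0 and 1. By the mixed form of fry, adjusted p was 0.00052 for FoxO1 targets, 0.000645 for ATF4 genes, 0.00062 for female-biased genes and 0.000742 for hepatocyte markers. It was 0.00451 for bile acid, 0.00885 for hormone receptor and energy-sensing and 0.0295 for autophagy genes. The other lists in this paragraph did not pass by that test. None of the lists in this paragraph was called by camera with all 8 libraries. Their signs differed between median, mean and camera for FoxO1 targets (median 0.08, mean -0.02), interferon-stimulated genes (-0.03 and 0.06) and erythroid genes (-0.01 and 0.12). Without control 1 adjusted p reached 0.0620 for Irs2, 0.0587 for Hnf4a and 0.0792 for Lrat. Without control 2 it reached 0.0981 for Nr0b2, 0.0610 for Rrm2 and 0.0868 for Dusp1, and without AgRP library 4 it was 0.0942 for Flt1.

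**Figure D3:**
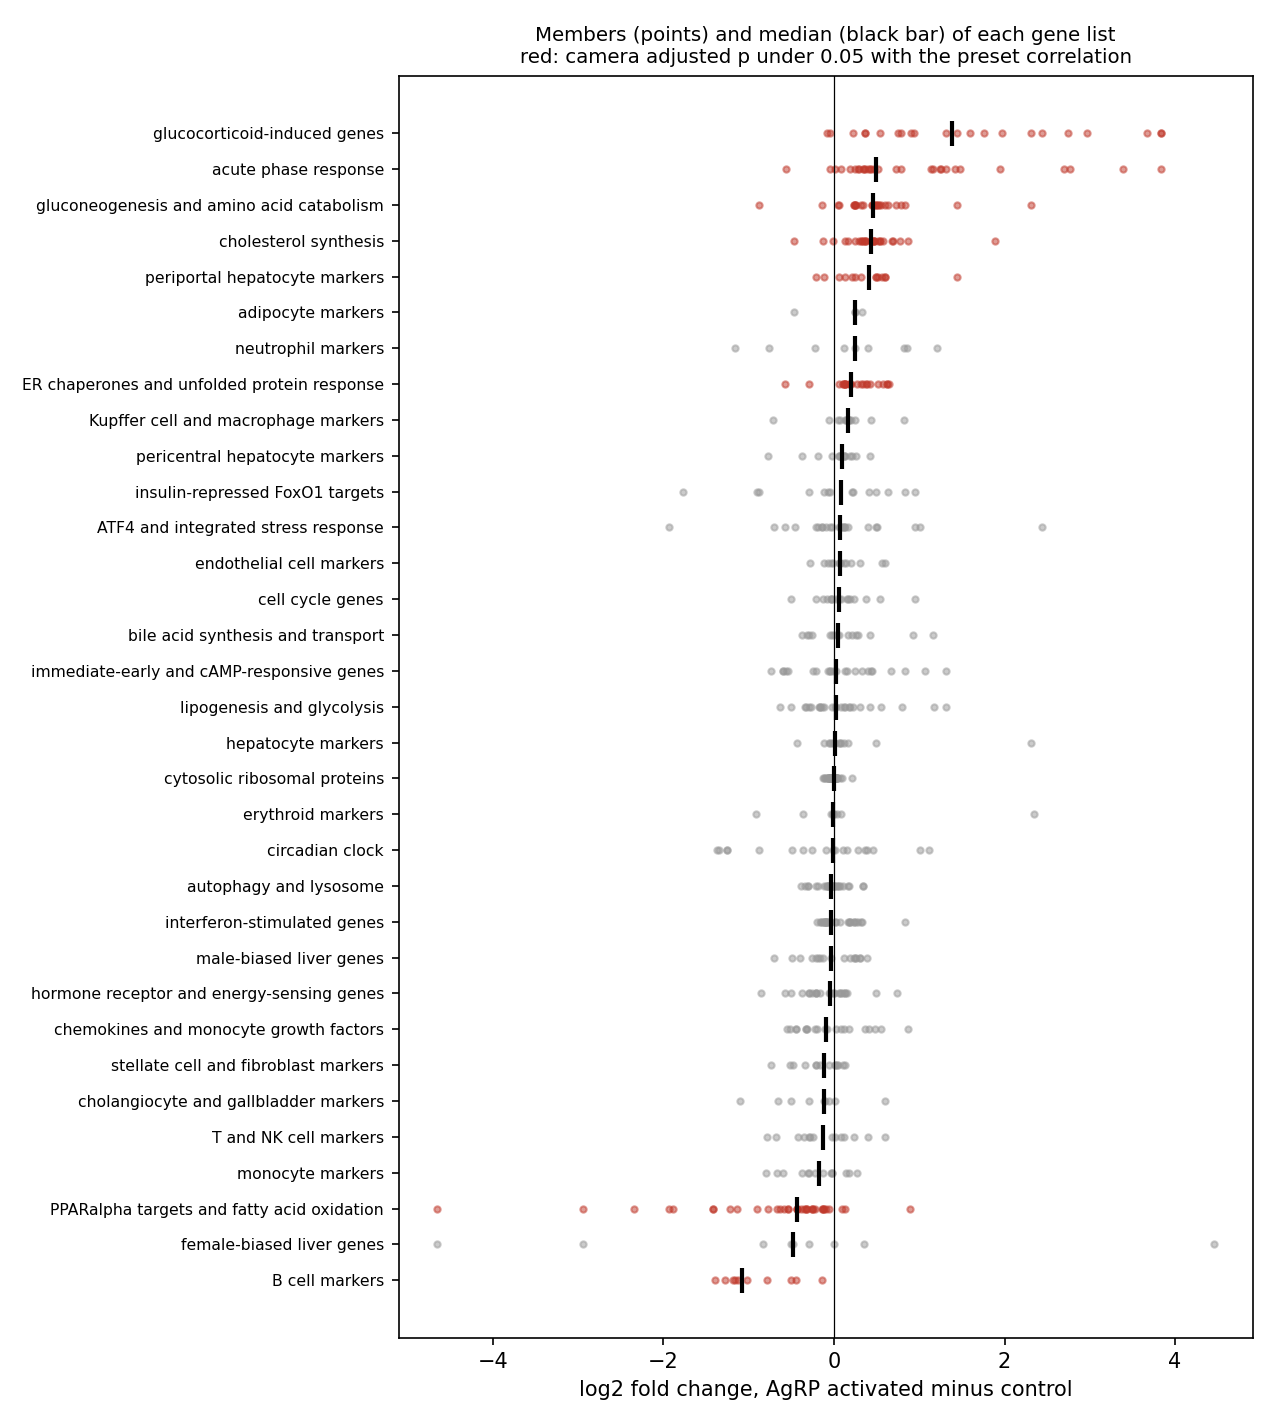
Log2 fold change (horizontal axis, AgRP activated minus control) of the members of 33 gene lists (rows), with points for genes and a black bar for the median, drawn in red where the camera adjusted p with a preset correlation was under 0.05. The medians ran from -1.07 for B cell markers to 1.38 for glucocorticoid-induced genes.

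Agrp and Xist have no row in the table, and Chrm3, the mouse gene of the muscarinic receptor type from which hM3Dq was engineered, had a log2 fold change of 0.84 ± 0.39 (SE, limma adjusted p = 0.259), so no liver gene checks the genotype. The study's description says that male and female mice were used, and the labels give no sex for these samples. Ddx3y, Uty, Eif2s3y and Kdm5d, which lie on chromosome Y, were expressed in all 8 libraries, with Ddx3y at 2404 ± 359 in AgRP activated and 2020 ± 79.9 scaled reads in control liver (SD, n = 4). Kdm5d ran from 404 to 480 scaled reads over the 8 libraries. These even levels, with no row for Xist, argue against a female among the 8 samples. In the authors' deposited table, adjusted p was under 0.05 for 1445 genes. Of the 771 genes called here, 770 were among them with the same sign. Both sets of calls come from the same reads, so this is not a separate check.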

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

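Dixon's test for a library apart from the other 3 of its group was planned; which results it would mark was not known. It was applied to 326 sets of 4 values (named genes, list scores and library measures) and marked 13. Chance marks about 1 in 20, so the marks were no more than chance gives. The named genes include those chosen after their values were seen, such as Nr1i3 below. Values below are log2 scaled reads with the gap to the nearest library as a share of the range.

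AgRP library 3 was apart from the other 3 in 6 of them. It was high for Ccl2 (7.35 against 3.36 to 3.86, share 0.875), Socs2 (8.61 against 6.82 to 7.03, share 0.879), the chemokine list score (8.06 against 6.98 to 7.16, share 0.836) and the interferon-stimulated list score (9.64 against 8.93 to 8.97, share 0.942). It was low for Dbp (10.2 against 11.2 to 11.3, share 0.901) and G6pc (12.4 against 13.4 to 13.5, share 0.938). In AgRP library 1 Rpl22 was high (share 0.843) and Cps1 low (17.3 against 17.5, share 0.967), and in AgRP library 4 Cx3cr1 was low (3.98 against 4.74 to 4.87, share 0.858). Among controls, Tat was high in control 3 (16.0 against 14.6 to 14.9, share 0.832), Sqle was high in control 1 (12.2 against 11.7, share 0.911), Nr1i3 was low in control 1 (11.8 against 12.3 to 12.4, share 0.889) and Kdm5d was low in control 2 (8.66 against 8.87 to 8.91, share 0.846).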

How the results depend on the processing

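The tests on recovered reads, and estimated correlations after a correction or without a library, were chosen after the data had been seen; the other settings were planned. No gene called with all 8 libraries changed sign under any setting. Genes higher and lower numbered 157 and 300 by limma without trend or robust settings, 669 and 775 by DESeq2, 611 and 775 at an adjusted p under 0.10, and 87 and 147 with a log2 fold change of at least 1 as well. Leaving out 1 library gave 139 to 266 higher and 218 to 385 lower genes; fewer samples were then fitted. For the other changes the cause was not tested. edgeR gave 772 calls, 751 shared with limma, quantile normalization 756 (679 shared) and a pseudocount of 0.1 753 (753 shared). With an estimated correlation 0 lists were called higher and 1 lower, B cell markers, which lost that call without 6 of the 8 libraries in turn. Of 69 named genes past the threshold, 33 kept their call without each library in turn. Residuals of same-numbered libraries correlated at 0.228, 0.283, -0.117 and 0.106, and only number 1 matched its own number best. Numbers 2 and 4 came close to their best match (0.283 against 0.292 and 0.106 against 0.116). The AgRP columns' numbers are not tied to a particular mouse, so this check cannot exclude a pairing of the samples. With the replicate block 265 genes were higher and 367 lower, 517 of them shared. A mean value of at least 1 removed no gene and tests nothing, and the filter's removal added 1 gene. The study's description says that male and female mice were used, but Y-linked genes were expressed in all 8 libraries, so sex as a covariate was not run. Depth limits genes with few reads, among them Greb1, Sult1e1 and Cyp2b10, with 2.43, 4.05 and 4.93 scaled reads on average in controls.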

Other observations

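The genes in this paragraph and the next were chosen after their values were seen, except those of the naming rule. Ppp1r3c (2.54 ± 0.36, SE, limma adjusted p = 0.00861) and Ppp1r3b (2.00 ± 0.37, SE, limma adjusted p = 0.0212), which bring protein phosphatase 1 to glycogen, rose, while their relative Ppp1r3g (-3.02 ± 0.52, SE, limma adjusted p = 0.0135) and Gys2, liver glycogen synthase (-0.71 ± 0.13, SE, limma adjusted p = 0.0158), fell. Pygl, glycogen phosphorylase, had a log2 fold change of 0.03 ± 0.16 (SE, limma adjusted p = 0.943). Ppp1r3b reached an adjusted p of 0.0629 without control 1.

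Cish (-2.48 ± 0.49, SE, limma adjusted p = 0.0282) and Socs2 (-2.43 ± 0.43, SE, limma adjusted p = 0.0183), feedback inhibitors of growth hormone signalling, fell, as did Onecut1 (-1.96 ± 0.24, SE, limma adjusted p = 0.00428), Igfals (-0.49 ± 0.09, SE, limma adjusted p = 0.0158) and Stat5a (-0.52 ± 0.13, SE, limma adjusted p = 0.0456). Igf1 (-0.11 ± 0.09, SE, limma adjusted p = 0.551) and the growth hormone receptor Ghr (-0.06 ± 0.09, SE, limma adjusted p = 0.772) did not pass. Without single libraries adjusted p reached 0.0780 for Cish and 0.0571 for Socs2 (control 4) and 0.113 for Stat5a (AgRP library 4). Cyp2b10 rose by 4.45 log2 units while Nr1i3, the receptor CAR that induces it, fell by 1.15 (SE 0.22, limma adjusted p = 0.0243), and Cyp2c37 (-0.13 ± 0.20, SE, limma adjusted p = 0.782) and Cyp3a11 (-0.21 ± 0.21, SE, limma adjusted p = 0.634) did not pass. Nr1i3 reached 0.0695 without control 2, and Cyp2b10 shares sequence with close paralogs.

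The tests of lipogenesis genes, other leukocytes and mitochondrial genes below were chosen after their results were seen; those of depth, GC content and length were set after the patterns but before their own outcomes. The count of splits was planned, but what would count against chance was written after the counts were seen. Of the 35 ways to divide the 8 libraries into 4 and 4, 1 gave as many genes as the real division, itself, with 771 against at most 2 for any other. A share of 1 in 35 is the smallest this count can give, and the other divisions mix the groups. The count argues against a chance division but cannot exclude it.

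The glucocorticoid-induced list ranked higher and the PPARalpha list lower at the preset correlation, but neither passed with an estimated correlation (adjusted p = 0.137 and 0.219). Removing each library's trend with GC content and exonic length left both lists past the threshold at the preset correlation (larger camera adjusted p = 9.94e-11, medians 1.41 and -0.38) while the genes called overall rose to 845, and thinning all libraries to the shallowest depth did as well (larger adjusted p = 3.65e-12, with 659 genes called). With an estimated correlation neither list passed after the trend was removed (adjusted p = 0.193 and 0.224) or at equal depth (0.137 and 0.186). Circulating glucocorticoid is not in the sources used here, so whether AgRP activation acted through it was not tested here. More food eaten by the activated mice is a candidate explanation, as a hypothesis, since food access is not in the sources used here. The lipogenesis and glycolysis list does not decide it, with a median of 0.0192 and members on both sides. Measured corticosterone, and mice kept without food after CNO, would bear on these.

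B cell markers were lower. Less blood or fewer leukocytes of every kind would lower T and NK cell genes alike. The B cell score minus the T and NK cell score, however, changed by -0.79. This difference was lower in 4 of 4 AgRP activated libraries than in any control. Its exact permutation p was 0.0286, the smallest possible (n = 4 per group), with an adjusted p of 0.0476 over 5 such scores. The B cell score alone had the same exact permutation p, with an adjusted p of 0.189 over the scores of all lists tested. The B cell list was taken up because it fell, so the difference is not a separate test of that fall. Hemoglobin genes Hba-a1 and Hbb-bs, chosen after their values were seen, had log2 fold changes of 0.01 ± 0.23 and 0.08 ± 0.20 (SE). The B cell score also separated from the Kupffer cell and erythroid scores, with differences of -1.05 and -1.03 (exact permutation p = 0.0286 for each). It did not separate from the monocyte and neutrophil scores (exact permutation p = 0.114 and 0.2, n = 4 per group). Those 2 scores themselves changed by -0.21 and 0.17 (exact permutation p = 0.657 and 0.743). Their spread between libraries was wide, so a fall of those cells too stays open. At equal depth the B cell list's median was -1.17 (SD over genes 0.485, n = 10), against -1.07 (SD 0.416) with all reads. Its camera adjusted p was then 4.89e-08 at the preset correlation and 0.0579 with an estimated correlation, which rose from -0.0247 to 0.0308. Whether fewer B cells or less of their RNA was present was not tested.

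Reads at 5 of 18 mitochondrial tRNA genes fell: mt-Ti, mt-Tq, mt-Tn, mt-Tc and mt-Ty, with a median log2 fold change of -0.86. These 5 lie in 2 clusters at 3706 to 3842 and 5089 to 5326 of the mitochondrial genome. The libraries were poly(A)-selected, so these reads need not measure mature tRNAs. All genes named in this paragraph were chosen after their values were seen. The other 13, none past the threshold, had a median of -0.01, from -0.61 to 0.62, and differed by position. Those between 1 and 5326 were lower except mt-Tm, from -0.61 for mt-Tv to -0.30 for mt-Tl1. Those between 9391 and 11741 (mt-Tg, mt-Tr, mt-Th, mt-Ts2 and mt-Tl2) were higher, by 0.39 to 0.62. Beside the clusters, mt-Tm (3845 to 3913) had 0.10 and mt-Ta (5018 to 5086) had -0.56, neither past the threshold. If the reads came from short RNAs, a lower yield of every kind would lower all 18. Of the 18, 8 had a 95% interval wholly above -0.86, among them mt-Te and mt-Tp at -0.01 and -0.02. The comparison cannot decide on short RNAs, because it is not known whether the reads came from tRNAs or from longer transcripts. It is also weak in other ways. The 5 were picked because they passed, and mt-Te and mt-Tp had means of 3077 and 6825 scaled reads, against 141 to 521 for the 5. Among those that did not pass, mt-Tv (-0.61), mt-Tf (-0.50) and mt-Tw (-0.46) were lower too. Abundant mitochondrial protein-coding genes had a median of 0.11, against a loss of mitochondrial reads. Counting by strand is not given in the sources used here, and antisense transcripts of neighbouring genes or precursor processing were not tested. Without control 2 mt-Ti, mt-Tn and mt-Ty had adjusted p of 0.0571, 0.0846 and 0.0535, and without control 4 mt-Tq had 0.0633.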
